A study of Homo sapiens and Mus musculus with 34 samples.

How the data were processed

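Gene expression was measured by RNA sequencing in 18 human libraries of the leukemia lines HL60 and MOLM13 and in 16 mouse libraries of hematopoietic progenitors. Per the labels' protocols, the human lines grew in RPMI medium with fetal bovine serum and received vitamin C for 0, 12 or 72 h, and the dose is not given in the sources used here. The mouse cells grew with stem cell factor and interleukins, and doxycycline at 1 ug/ml turned off an shRNA against Tet2, per the labels. The number 39 or 46 in each mouse label is not explained there, and the series' design text speaks of 2 mouse lines.

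The submitters' processing notes name bcl2fastq, STAR, featureCounts and DESeq2, without versions, roles or order, and the builds hg19 (GRCh37) and mm10 (GRCm38). The strand setting, the annotation release and any filter are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart. The authors deposited raw counts per gene symbol, as whole numbers, for 55736 human and 47480 mouse genes, of which 29563 and 24290 had a count. They also deposited a normalized signal, which equals the raw counts divided by 1 factor per library to within 0.000624% in the human and 0.000886% in the mouse table. All tests used the raw counts. No mitochondrially encoded gene was found in either table (0 members).

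Total counts per library ran from 14445453 to 27163017 in the human and from 18058268 to 75366205 in the mouse libraries. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.97 in every human and 39.3 in every mouse pair, so each library counted as 1 replicate. The first principal component held 87.7% of the variance of the human and 61.2% of that of the mouse libraries. The floor of 3 counts, set for genes with no count in a group, covers counting error only.

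The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM scaling, genes kept by filterByExpr and Benjamini-Hochberg adjustment at 0.05. It was fitted to all 18 human libraries with a term per line and time (14128 genes), and to all 16 mouse libraries with a term per label and day (13766 genes). Standard errors of log2 fold changes are approximate. Each was the absolute log2 fold change divided by the square root of the F statistic of the same fit. In the human libraries each time was compared with the others within a line, the lines were compared at 0 h, and the difference of their responses was tested. In the mouse libraries plus was compared with minus over the 4 days and at each day, the change of that difference with day was tested, and day 14 was compared with day 3.

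For each species 33 gene lists were tested with camera (limma 3.58.1, voom weights) at a preset correlation between genes of 0.01, with adjustment over the lists within each comparison. Of the list calls at that preset, 160 in all, 1 held with the correlation estimated from the data, that of G1/S and DNA replication in the difference between the lines at 12 h. The number of members called was counted with adjustment over all genes and adjusted over the list alone.

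Genes to name were chosen by rule. In each line at 12 and 72 h against 0 h and over the mouse days, these were the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 1. Libraries of the groups had not to overlap, or, in the mouse, at least 7 of the 8 pairs had to share the sign. Up to 4 called members of each list (2 if none was called) and TET1, TET2, TET3 and TDG were added, and 4 rises and 4 falls in every other comparison, or the smallest p where a test had no single fold change. These groups, designs, lists, naming rules and most alternatives were set before the data were examined. A further rule, chosen after seeing the data, asked for at least 10 CPM in a group of the line. MALAT1, Malat1, Mki67, the remaining genes of the plots, and Tet2 at day 14 were named after their values were seen, except where a rule took them.

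Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a test for a fold change above 1.2, fits to 1 line or day alone, each library left out in turn and, in the mouse, the number 39 or 46 as a block. Chosen after seeing the data were removal of the trend with transcript length, leaving out the 72 h libraries 15 and 27, leaving out day 10 minus library 46, a level of at least 1 CPM, and every library thinned to the smallest total. Lengths were medians over the human transcripts of a symbol in the GENCODE basic annotation, release v29, found for 95.6% of human and, by the same symbol in capitals, 86.2% of mouse genes over 500 counts. Its human build differs from hg19, so no coordinates are given. The length trend of a library is the Spearman correlation across genes of its log2 difference from the other 0 h libraries of its line with transcript length, over genes with more than 500 counts in total.

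The mouse numbers were taken to pair the libraries. Of 28 correlations of deviations from the group means between libraries of number 39, the lowest was 0.495 and the highest 0.906, and those of number 46 repeat them, since the deviations within a group of 2 mirror each other. The number came from the labels, and its meaning was not given in the sources used here. It also went with transcript length. In the mouse, the length trend was taken between the 2 libraries of a group. For library 39 it was -0.122 in day 10 plus and ran from 0.104 to 0.414 in the other groups, highest in day 10 minus. This trend was not removed in the mouse fits, and the block takes the number to act alike in every group. Blocked values stand beside a result where they change its calls. Some genes that the naming rule took are not reported here.

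The procedure was tested on simulated counts with 200 changed genes. For HL60 at 12 h (13911 genes) it recovered 50.7% of 1.5-fold, 83.6% of 2-fold and 98.5% of 4-fold changes with 9 false calls. At 72 h it recovered 43.3%, 86.6% and 98.5% in HL60 (13901 genes, 4 false calls) and 40.3%, 85.1% and 100% in MOLM13 (13921 genes, 8 false calls). For the mouse mean over days it recovered 71.6%, 89.6% and 98.5% (13622 genes, 9 false calls), and 97.0%, 100% and 100% with the block (13589 genes, 13 false calls). At day 14 with the block these were 46.3%, 83.6% and 98.5% (13595 genes, 5 false calls). Each simulated library was drawn independently around the level of its base group, 0 h of its line or minus of its day. The simulated counts thus held no length trend, no library standing apart and no correlation between genes. Recovery in the real libraries may differ.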

Results

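RNA was sequenced from 2 human myeloid leukemia lines treated with vitamin C and from mouse hematopoietic progenitors that carried a doxycycline-regulated short hairpin RNA (shRNA) against Tet2, an enzyme that oxidises 5-methylcytosine in DNA. HL60 is a promyelocytic and MOLM13 a monocytic leukemia line. Each line was sampled at 0, 12 and 72 h of vitamin C with 3 libraries per time, 18 in all. The 16 mouse libraries were labelled plus or minus doxycycline at days 3, 7, 10 and 14, with 2 libraries per group that carried the numbers 39 and 46. Total counts per library ran from 14445453 to 27163017 in the human and from 18058268 to 75366205 in the mouse libraries. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Values after ± are standard errors for log2 fold changes and standard deviations for counts-per-million (CPM) values.

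In MALAT1 and in the trend with transcript length, a pair of human libraries stood apart from the rest of their groups. HL60 library 15 at 72 h held the nuclear RNA MALAT1 at 960 CPM, against 338 and 345 CPM in the other 72 h libraries and 220 to 313 CPM at 0 h. MOLM13 library 27 at 72 h held MALAT1 at 496 CPM, against 135 and 221 CPM in the other 72 h libraries. In both, longer transcripts were lower relative to the 0 h libraries, with a Spearman correlation across genes, which are not independent replicates, of -0.654 in library 15 and -0.540 in library 27. The 12 h libraries shared this trend with length, at -0.431 to -0.486 in HL60 and -0.343 to -0.385 in MOLM13, as did MOLM13 library 25 at 72 h (-0.381). MALAT1 stood at 894 to 1347 CPM in HL60 at 12 h. Cytosolic ribosomal protein genes took 6.69% of the counts in library 15, 6.13% to 6.81% in HL60 at 12 h and 3.80% to 4.70% in the other HL60 libraries. Some 0 h libraries also differed from their groups. The chi-square per degree of freedom was 28.1 and 18.2 for library 27 against the other 72 h libraries. It was 26.4 and 17.8 for HL60 0 h library 1, and 17.6 and 25.4 for MOLM13 0 h library 18. For library 15 it was 88.4 and 113.6.

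The comparison of 12 h with 0 h asked which genes changed early after vitamin C, a cofactor of iron-dependent and 2-oxoglutarate-dependent dioxygenases. In HL60, the glycolytic aldolase gene ALDOC went from 64.5 ± 24.5 CPM at 0 h to 3.18 ± 0.82 CPM at 12 h (n = 3 per group), a log2 fold change of -4.33 ± 0.36. The fatty acid desaturase gene FADS2 (-3.30 ± 0.25), the sialidase gene NEU3 (-3.45 ± 0.34) and the matrix protein gene SPARC (-3.30 ± 0.15) also fell. The lipid-associated phospholipase gene PLA2G7 (2.78 ± 0.23) and the galectin gene LGALS3 (2.45 ± 0.20) rose, as did the semaphorin gene SEMA6B (2.31 ± 0.25), the complement gene C3 (2.15 ± 0.25) and the kinase gene SGK1 (2.01 ± 0.19). The adjusted p of these 9 genes was at most 3.3e-06 in edgeR. The heat shock gene HSPA1B (2.02 ± 0.20), whose reads cannot be told from those of its near-identical neighbour HSPA1A, and MALAT1 (2.08 ± 0.39) were higher as well. Of 14128 genes tested, 6688 changed, 3255 higher and 3433 lower, and 678 and 1027 of these differed by more than 2-fold. Without a filter on low counts the split was 2658 higher and 3769 lower. The line had no library without vitamin C at 12 h, so time in culture goes with treatment.

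Genes of lipid synthesis and of the hypoxia response fell in HL60 at 12 h. List members given as examples for this comparison passed edgeR's test at an adjusted p of at most 0.00019, that of RPL35. Of 31 measured genes for cholesterol synthesis and other targets of SREBP, 26 fell and 0 rose (26 and 0 adjusted over the list alone), with a median log2 fold change of -1.15. They included the desaturase gene FADS1 at -2.63 ± 0.19 and the transcription factor gene SREBF1 at -1.75 ± 0.11. The list fell against other genes (camera adjusted p = 1.2e-13), and the call did not hold with the correlation between genes estimated (adjusted p = 0.27 with an estimated correlation). Of 33 hypoxia and HIF targets, 25 fell and 2 rose (26 and 2 adjusted over the list alone, camera adjusted p = 4.3e-07, and adjusted p = 0.36 with an estimated correlation). Examples were the collagen hydroxylase gene P4HA1 at -1.96 ± 0.18 and DDIT4, an inhibitor of mTOR signalling, at -1.75 ± 0.15. Glycolysis genes fell in 12 of 20 cases and rose in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.0087, and adjusted p = 0.56 with an estimated correlation). Examples were PFKL at -1.11 ± 0.12 and PGK1 at -0.68 ± 0.09. In library 15 at 72 h, the median of the SREBP targets lay 0.01 and that of the hypoxia targets -0.09 log2 from the other 72 h libraries.

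Genes of DNA replication and of the DNA damage response were lower in HL60 at 12 h. Of 31 G1/S and replication genes, 20 fell and 1 rose (20 and 1 adjusted over the list alone). Examples were the ribonucleotide reductase gene RRM2 (-0.95 ± 0.09), the cell cycle transcription factor gene E2F2 (-1.13 ± 0.12) and the cyclin gene CCNE2 (-1.35 ± 0.15). The list fell (camera adjusted p = 3.5e-06, and adjusted p = 0.29 with an estimated correlation). Of 27 genes of the DNA damage response and homologous recombination, 20 fell and 3 rose (20 and 3 adjusted over the list alone, camera adjusted p = 4.8e-05, and adjusted p = 0.36 with an estimated correlation). Examples were BRCA1 at -1.44 ± 0.17, FANCI at -1.02 ± 0.11 and FANCD2 at -0.93 ± 0.11. FANCD2 was at -0.57 with the trend with transcript length removed. Base excision repair genes rose in 6 and fell in 4 of 20 cases (6 and 4 adjusted over the list alone, camera adjusted p = 0.71), and their list was not called. G2/M genes went both ways, 14 lower and 4 higher of 31 (15 and 5 adjusted over the list alone, camera adjusted p = 0.0089, and adjusted p = 0.47 with an estimated correlation). Examples were the mitotic kinesin gene KIF2C at -0.72 ± 0.09 and the ubiquitin-conjugating enzyme gene UBE2C at 0.86 ± 0.12, or 0.44 with the length trend removed. In library 15 the DNA damage list also lay below the other 72 h libraries, with a median of -0.37 log2, and the G1/S list lay at 0.13.

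Genes of ribosome assembly, protein folding and the antioxidant response rose in HL60 at 12 h. Of 31 MYC targets and ribosome biogenesis genes, 18 rose and 4 fell (18 and 4 adjusted over the list alone, camera adjusted p = 0.0021, and adjusted p = 0.56 with an estimated correlation). Examples were RRS1 at 1.25 ± 0.12 and PA2G4 at 0.86 ± 0.11. Of 25 heat shock and unfolded protein genes, 16 rose and 3 fell (16 and 3 adjusted over the list alone, camera adjusted p = 0.0018, and adjusted p = 0.47 with an estimated correlation). Examples were the chaperone gene HSP90AA1 at 0.89 ± 0.12 and the mitochondrial chaperonin gene HSPE1 at 1.09 ± 0.15, or 0.61 with the length trend removed. Of 23 NRF2 and oxidative stress targets, 13 rose and 2 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.0059, and adjusted p = 0.27 with an estimated correlation). Examples were the quinone reductase gene NQO1 at 1.12 ± 0.11 and the catalase gene CAT at -0.66 ± 0.09. The iron storage gene FTH1, which has processed copies that can share its reads, stood at 1.45 ± 0.19. These lists moved the same way in library 15 against the other 72 h libraries, by a median of 0.37, 0.19 and 0.22 log2 in the order given.

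Cytosolic ribosomal protein genes, which have many processed copies, rose in 23 of 33 cases and fell in 0 (28 and 1 adjusted over the list alone, camera adjusted p = 5.7e-06, and adjusted p = 0.65 with an estimated correlation). Examples were RPS6 at 0.92 ± 0.15 and RPL35 at 1.06 ± 0.19. The list call was lost with the length trend removed (adjusted p = 0.078), where RPL35 stood at 0.56. Nuclear genes of oxidative phosphorylation rose in 17 and fell in 4 of 33 cases (20 and 4 adjusted over the list alone, camera adjusted p = 0.0095, adjusted p = 0.73 with an estimated correlation, and 0.82 with the length trend removed). Examples were NDUFB5 at 1.07 ± 0.15 and SDHA at -0.82 ± 0.10. In library 15 the medians of these lists lay 0.77 and 0.57 log2 above the other 72 h libraries.

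Myeloid genes moved in both directions in HL60 at 12 h. Of 37 genes of late myeloid differentiation, 17 rose and 9 fell (18 and 9 adjusted over the list alone). The formyl peptide receptor gene FPR1 rose by 2.01 ± 0.18 and the monocyte marker gene CD14 by 1.83 ± 0.19, and the secondary granule gene LTF changed by -4.29 ± 0.40. The list was called higher (camera adjusted p = 0.031, and adjusted p = 0.65 with an estimated correlation), but not without 0 h library 2 (adjusted p = 0.116) or 12 h library 5 (adjusted p = 0.0540), nor with the length trend removed (adjusted p = 0.13). Of 18 early granule genes, 8 fell and 3 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.16). Examples were the protease gene CTSG at -1.53 ± 0.14, the myeloperoxidase gene MPO at -1.18 ± 0.13 and the granulocyte transcription factor gene CEBPA at -1.61 ± 0.21. The list was not called. The eosinophil peroxidase gene EPX stood at -2.69 ± 0.19. Of 26 inflammatory and NF-kB targets, 13 rose and 3 fell (13 and 5 adjusted over the list alone, camera adjusted p = 0.035, and adjusted p = 0.63 with an estimated correlation). Examples were BCL2A1 at 1.54 ± 0.15 and CCL2 at 1.99 ± 0.21. That call was lost without 0 h library 2 (adjusted p = 0.109), 12 h library 5 (0.0540) or 12 h library 7 (0.0618), and with the length trend removed (0.079). The late myeloid and NF-kB medians lay 0.19 and 0.12 log2 higher in library 15 than in the other 72 h libraries.

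**Figure D1:**
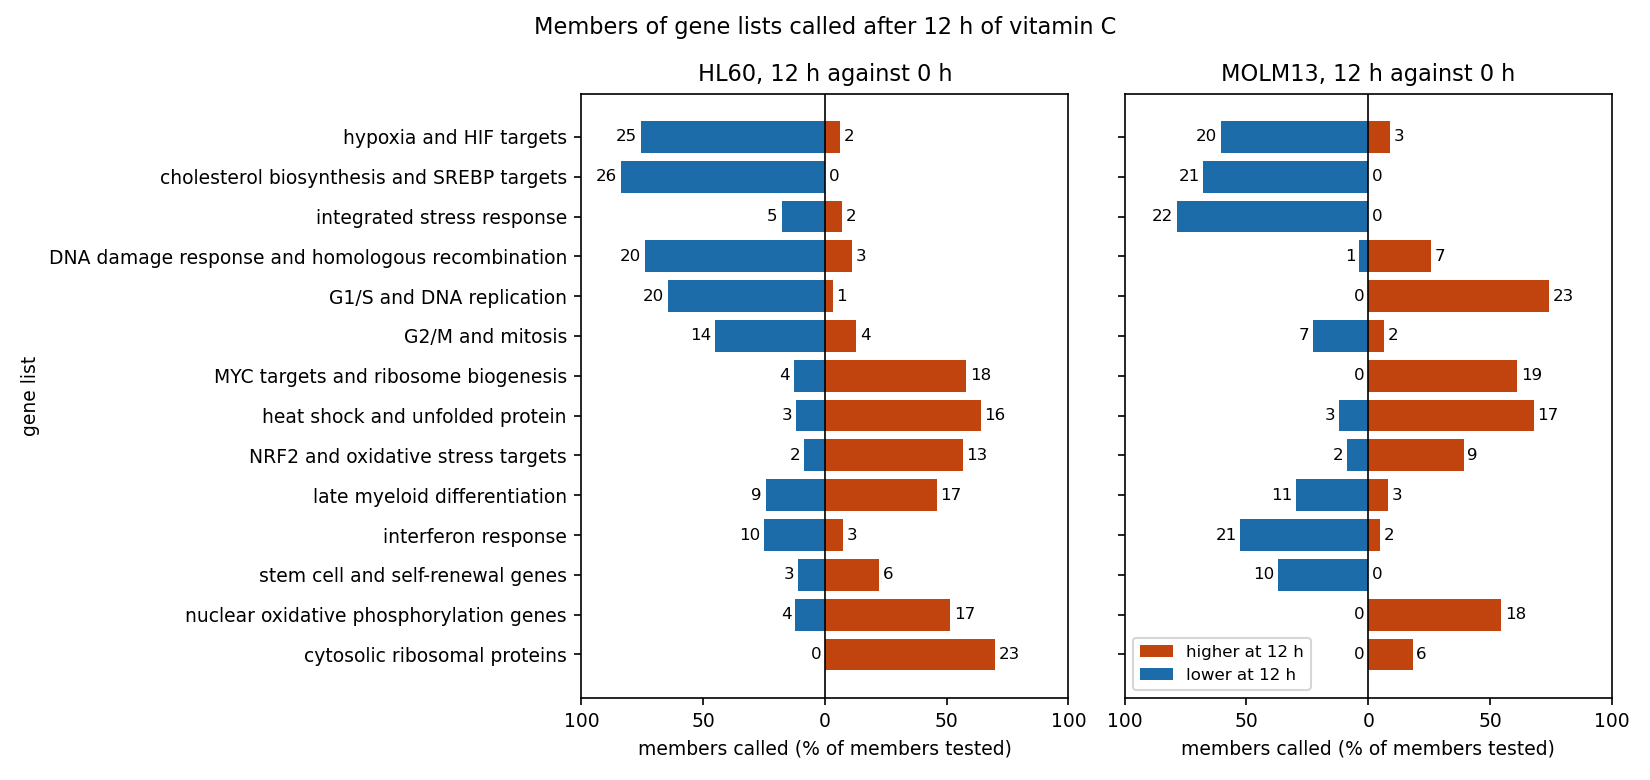
Percent of measured members of 14 gene lists called higher (right) or lower (left) at 12 h of vitamin C against 0 h in HL60 and MOLM13, with the number of genes beside each bar. In HL60, 20 G1/S genes were lower and 1 higher, and in MOLM13 23 were higher and 0 lower.

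In MOLM13, the peptide hormone gene ADM went from 28.1 ± 14.5 CPM at 0 h to 2.79 ± 0.57 CPM at 12 h (n = 3 per group), a log2 fold change of -3.31 ± 0.30. TBC1D30 (-4.56 ± 0.31), the creatine transporter gene SLC6A8 (-3.96 ± 0.51), TMEM45A (-3.96 ± 0.35) and CHAC1, which degrades glutathione (-3.71 ± 0.64), fell as well. CHAC1 ranged from 43 to 617 counts over the 0 h libraries, against 24 to 34 at 12 h. SLC6A8 ranged from 330 to 1420 counts at 0 h, against 41 to 84 at 12 h. The size of both falls was therefore uneven. The transaminase gene AGXT (-5.64 ± 0.45) was left with 11 counts over the 12 h libraries. The cyclin gene CCNE1 rose from 14.2 ± 0.76 to 32.6 ± 0.85 CPM (1.19 ± 0.09), and CRELD2 (1.26 ± 0.16) and MANF (1.10 ± 0.16), which act in the endoplasmic reticulum, rose by similar amounts. In edgeR, the adjusted p of these genes was at most 0.00058. Of 14128 genes, 3784 changed, 1871 higher and 1913 lower, and 102 and 489 of these differed by more than 2-fold. The count was 2498 without 0 h library 16, 2337 without 12 h library 21 and 2263 without 12 h library 22, and 6004 when the 72 h libraries 15 and 27 were left out. With each line fitted alone, 5115 genes were called in MOLM13 and 5728 in HL60. The main fit shares its spread over all 18 libraries, so its counts do not rank the lines by breadth of response. As in HL60, no MOLM13 library without vitamin C was sampled at 12 h.

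Hypoxia, lipid and amino acid stress genes fell in MOLM13 at 12 h. List members given as examples for this comparison passed edgeR's test at an adjusted p of at most 0.0023, that of SDHB. Of 33 hypoxia and HIF targets, 20 fell and 3 rose (21 and 4 adjusted over the list alone, camera adjusted p = 3e-07, and adjusted p = 0.25 with an estimated correlation). Examples were the growth factor gene VEGFA at -1.06 ± 0.13 and DDIT4 at -1.56 ± 0.15. SLC2A3, which encodes a transporter of glucose and oxidised vitamin C, stood at -2.14 ± 0.21. Of 31 SREBP targets, 21 fell and 0 rose (23 and 0 adjusted over the list alone, camera adjusted p = 1.1e-07, and adjusted p = 0.25 with an estimated correlation). Examples were FADS2 at -1.51 ± 0.23, SCD at -0.96 ± 0.16, SREBF1 at -0.78 ± 0.10 and SREBF2 at -0.75 ± 0.11. Of 28 integrated stress response genes, 22 fell and 0 rose (25 and 0 adjusted over the list alone, camera adjusted p = 2.3e-07, and adjusted p = 0.47 with an estimated correlation). Examples were the mitochondrial folate enzyme gene ALDH1L2 at -1.45 ± 0.29 and the hormone gene STC2 at -2.56 ± 0.52. The cystine transporter gene SLC7A11 stood at -2.13 ± 0.42. In library 27 at 72 h, the medians of these lists lay -0.10, -0.39 and 0.73 log2 from the other 72 h libraries, in the order given.

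Replication and folding genes rose in MOLM13 at 12 h. Of 31 G1/S and replication genes, 23 rose and 0 fell (25 and 0 adjusted over the list alone, camera adjusted p = 3.4e-13, and adjusted p = 0.083 with an estimated correlation). Examples were the replication licensing gene CDC6 at 0.74 ± 0.08 and the thymidylate synthase gene TYMS at 0.69 ± 0.08. Of 20 base excision repair genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00024, and adjusted p = 0.27 with an estimated correlation). Examples were the uracil glycosylase gene UNG, also a member of the G1/S list, at 0.77 ± 0.09 and the flap endonuclease gene FEN1 at 0.81 ± 0.11. Heat shock and unfolded protein genes rose in 17 and fell in 3 of 25 cases (19 and 3 adjusted over the list alone, camera adjusted p = 6.2e-08, and adjusted p = 0.17 with an estimated correlation). Examples were DNAJA1 at 0.80 ± 0.11, HSP90B1 at 0.68 ± 0.09 and EDEM1 at -1.14 ± 0.15. MYC targets and ribosome biogenesis genes rose in 19 and fell in 0 of 31 cases (21 and 1 adjusted over the list alone, camera adjusted p = 6.4e-07, and adjusted p = 0.25 with an estimated correlation). Examples were RRS1 at 0.71 ± 0.12 and PA2G4 at 0.60 ± 0.11. NRF2 targets rose in 9 and fell in 2 of 23 cases (11 and 2 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.17 with an estimated correlation). Examples were the thioredoxin gene TXN at 0.85 ± 0.14 and its inhibitor TXNIP at -0.65 ± 0.11. In library 27 the G1/S, base excision repair, heat shock, MYC and NRF2 medians lay -0.07, 0.16, -0.10, 0.05 and 0.02 log2 from the other 72 h libraries, and the base excision repair median at 12 h was 0.21.

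Oxidative phosphorylation genes rose in 18 and fell in 0 of 33 cases in MOLM13 (22 and 1 adjusted over the list alone, camera adjusted p = 1.9e-06, and adjusted p = 0.47 with an estimated correlation). Examples were NDUFA4 at 0.69 ± 0.13 and SDHB at 0.53 ± 0.11. Ribosomal protein genes rose in 6 and fell in 0 of 33 cases (1 and 0 adjusted over the list alone). Their list was called higher (camera adjusted p = 5.7e-05, and adjusted p = 0.53 with an estimated correlation). In library 27 the medians of these lists lay 0.13 and 0.24 log2 above the other 72 h libraries.

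Some interferon, stem cell and immediate-early genes fell in MOLM13 at 12 h. Of 40 interferon response genes, 21 fell and 2 rose (23 and 2 adjusted over the list alone, camera adjusted p = 0.00053, and adjusted p = 0.47 with an estimated correlation). Examples were IFITM1 at -2.02 ± 0.40 and TRIM22 at 0.60 ± 0.12. IFIT1 stood at -2.72 ± 0.56, and at -1.20 without 0 h library 18. Of 27 stem cell and self-renewal genes, 10 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 5.7e-05, and adjusted p = 0.21 with an estimated correlation). Examples were the transcription factor genes MEF2C at -0.79 ± 0.14 and MEIS1 at -0.59 ± 0.12 and the receptor gene FLT3 at -0.54 ± 0.10. Immediate-early genes fell in 10 and rose in 0 of 24 cases (11 and 0 adjusted over the list alone, camera adjusted p = 0.0053, and adjusted p = 0.53 with an estimated correlation). Examples were KLF6 at -0.71 ± 0.13 and ZFP36 at -0.89 ± 0.18. Late myeloid genes fell in 11 and rose in 3 of 37 cases (11 and 4 adjusted over the list alone, camera adjusted p = 0.065). Examples were the integrin gene ITGAM at -1.06 ± 0.17 and the receptor gene CSF1R at -1.04 ± 0.17. Their list was not called. The interferon, stem cell and immediate-early medians lay -0.21, 0.05 and 0.17 log2 from the other 72 h libraries in library 27.

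Vitamin C is a cofactor of the TET enzymes, so their transcripts were followed in both lines. TET2 went from 152 ± 10.4 to 73.8 ± 5.97 CPM in HL60 at 12 h (-1.05 ± 0.28, adjusted p = 0.0055, n = 3 per group) and from 62.4 ± 4.36 to 29.98 ± 2.43 CPM in MOLM13 (-1.06 ± 0.29, adjusted p = 0.012). With the length trend removed it fell less, to -0.41 and -0.67, and the MOLM13 call was lost without 12 h library 21 (adjusted p = 0.051). TET1 stood at -0.92 ± 0.33 in HL60 (adjusted p = 0.027), a call lost without 0 h library 2 (0.075) or 4 (0.053), 12 h library 5 (0.071) or 7 (0.080), and with the length trend removed (-0.31, adjusted p = 0.31). In MOLM13, TET1 was not called at 0.36 ± 0.42 (adjusted p = 0.55). TET3 was not called in HL60 (-0.33 ± 0.19, adjusted p = 0.16), where its direction turned with the length trend removed (0.24, adjusted p = 0.031), or in MOLM13 (-0.47 ± 0.19, adjusted p = 0.066), where it passed without the 72 h libraries 15 and 27 (-0.46, adjusted p = 8.1e-05). The glycosylase gene TDG was not called in HL60 (0.00 ± 0.11, adjusted p = 1) or MOLM13 (0.18 ± 0.11, adjusted p = 0.21). At 72 h against 0 h, TET2 was not called in HL60 (-0.32 ± 0.28, adjusted p = 0.69) or MOLM13 (-0.55 ± 0.29, adjusted p = 0.55), and library 15 held TET2 at 46.9 CPM of raw total against 144 and 159 CPM in the other HL60 libraries of that time. TET1, TET3 and TDG were not called at 72 h in either line.

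Of 15 TET and DNA methylation genes, 7 fell and 3 rose in HL60 at 12 h (7 and 3 adjusted over the list alone, camera adjusted p = 0.19). Examples were the maintenance methyltransferase gene DNMT1 at -1.24 ± 0.12 and its partner UHRF1 at -0.89 ± 0.15. The list was not called. In MOLM13, 3 fell and 2 rose (4 and 3 adjusted over the list alone, camera adjusted p = 0.75). Of 26 other 2-oxoglutarate-dependent dioxygenase genes, 16 fell and 3 rose in HL60 (16 and 3 adjusted over the list alone). Examples were the histone demethylase genes KDM2B at -0.89 ± 0.10 and KDM5B at -1.06 ± 0.15, or -0.60 with the length trend removed. The HL60 list fell (camera adjusted p = 0.0023, and adjusted p = 0.33 with an estimated correlation), but not with the length trend removed (adjusted p = 0.079). In MOLM13, 10 fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.0052, and adjusted p = 0.25 with an estimated correlation). Examples were KDM6B at -1.10 ± 0.15, KDM3A at -0.91 ± 0.14 and the HIF hydroxylase gene EGLN1 at -0.71 ± 0.12, or -0.42 with the length trend removed. In library 15 the medians of the TET and the other dioxygenase lists lay -0.34 and -0.23 log2 from the other 72 h libraries.

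**Figure D2:**
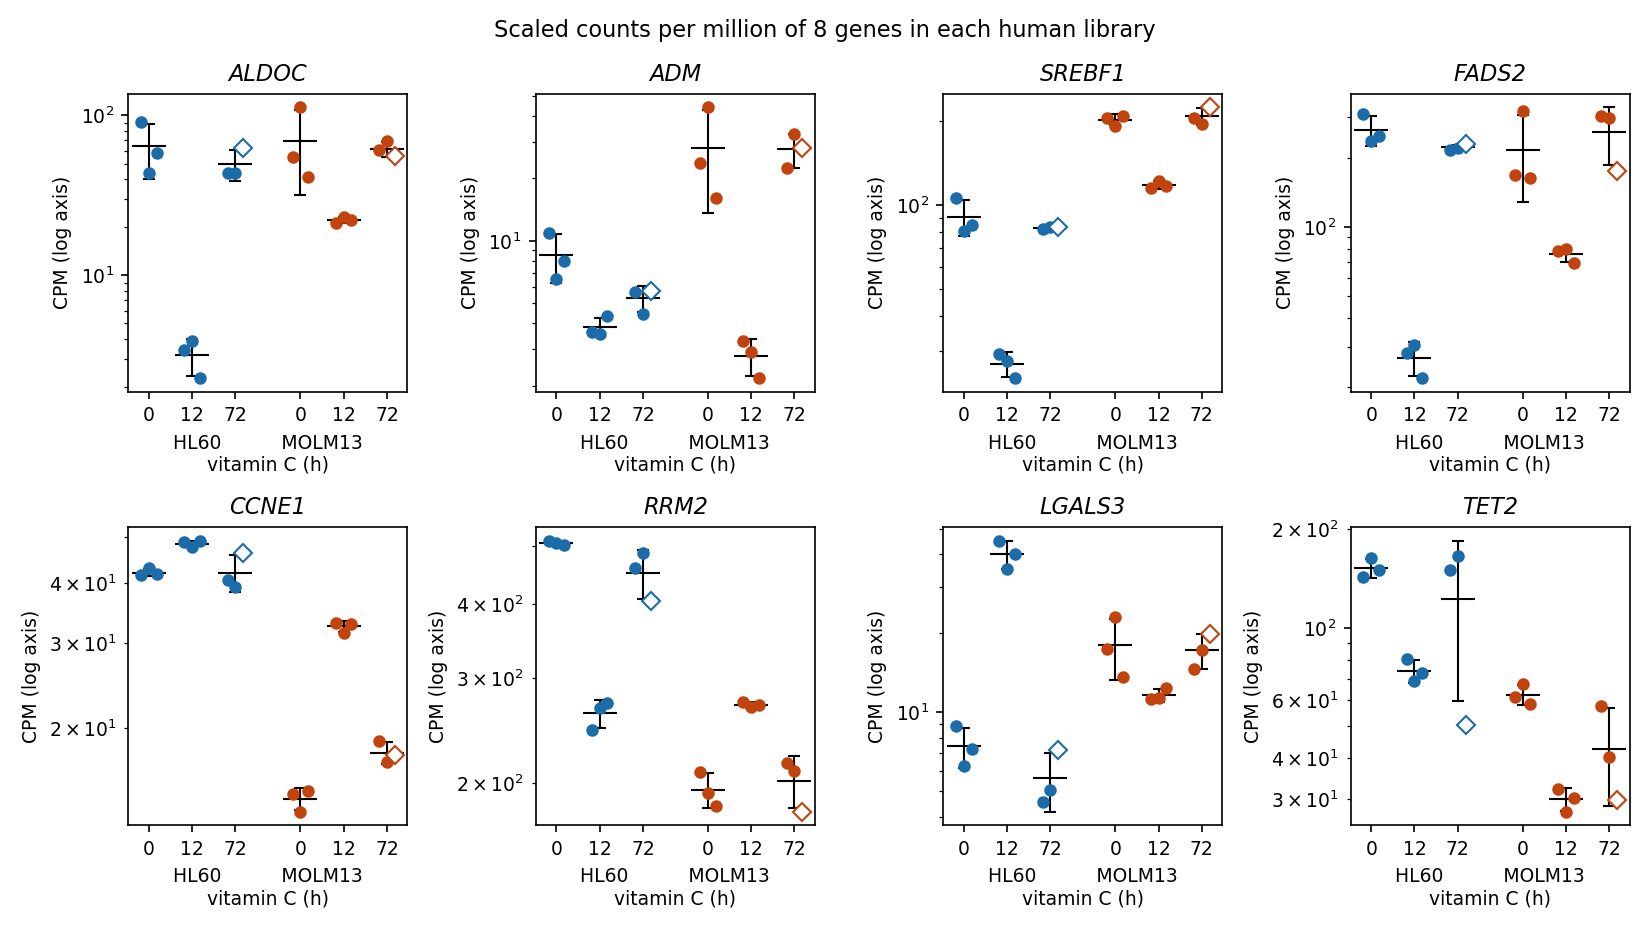
CPM after scaling (log axis) of 8 genes in each of 18 human libraries by hours of vitamin C, with HL60 in blue and MOLM13 in orange, dashes for the mean, bars for the SD (n = 3) and open diamonds for libraries 15 and 27. ALDOC in HL60 averaged 64.5, 3.18 and 49.7 CPM at 0, 12 and 72 h, and CCNE1 in MOLM13 averaged 14.2, 32.6 and 17.8 CPM.

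The responses of the lines at 12 h differed in direction for the replication genes. Of 31 G1/S genes, 28 responded lower in HL60 than in MOLM13 and 0 higher (29 and 0 adjusted over the list alone, camera adjusted p = 1.7e-24, and adjusted p = 0.0075 with an estimated correlation). The median difference was -0.95 log2. LGALS3 differed by 3.07 ± 0.27 log2, the immune gene FGL2 by 2.41 ± 0.36, and the metallothionein genes MT1X and MT2A, members of a family with similar sequences, by 2.29 ± 0.40 and 2.19 ± 0.43, all more positive in HL60. ALDOC (-2.69 ± 0.46), the transferrin receptor gene TFRC (-2.31 ± 0.37) and the perlecan gene HSPG2 (-2.26 ± 0.34) were more negative in HL60. DNA damage genes differed by a median of -0.71 log2 (0 higher and 15 lower of 27, 0 and 17 adjusted over the list alone, camera adjusted p = 1.8e-08, and adjusted p = 0.15 with an estimated correlation). Integrated stress response genes were more positive in HL60, by a median of 0.73 (10 higher and 0 lower of 28, 12 and 0 adjusted over the list alone, camera adjusted p = 0.0023, and adjusted p = 0.78 with an estimated correlation). SREBP targets were more negative, by a median of -0.60 (0 higher and 12 lower of 31, 1 and 18 adjusted over the list alone, camera adjusted p = 8.7e-08, and adjusted p = 0.51 with an estimated correlation). Hypoxia targets were not called different (3 higher and 6 lower of 33, 5 and 7 adjusted over the list alone, camera adjusted p = 0.341).

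In edgeR's test of the difference, 2628 of 14128 genes passed, 1136 more positive and 1492 more negative in HL60. The count was 4649 without the 72 h libraries 15 and 27. Over 14128 genes, the 12 h changes of the lines correlated with Pearson r = 0.302 and Spearman rho = 0.399, and with r = 0.249 after the length trend was removed, where genes are not independent replicates. Both lines called 1053 genes higher and 856 lower, against 431 and 465 expected for independent lists, and 263 genes were called in opposite directions against 895 expected.

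At 72 h, most of the plotted genes stood nearer their 0 h than their 12 h level. In HL60, ALDOC was back at 49.7 ± 11.01 CPM and LGALS3 at 5.60 ± 1.42 CPM against 7.43 ± 1.31 CPM at 0 h (n = 3 per group). In MOLM13, ADM stood at 27.7 ± 5.11 CPM and CCNE1 at 17.8 ± 0.93 CPM. ADM in HL60 (8.50 ± 2.23, 3.84 ± 0.42 and 5.29 ± 0.75 CPM at 0, 12 and 72 h) and TET2 in MOLM13 (62.4 ± 4.36, 29.98 ± 2.43 and 42.6 ± 14.1 CPM) stood nearer their 12 h level. In edgeR, 7 of 14128 genes were called in HL60 at 72 h against 0 h, among them the granule genes LCN2 (-2.65 ± 0.33, adjusted p = 0.017), DEFA4 (-1.12 ± 0.17, adjusted p = 0.042) and EPX (-0.98 ± 0.17, adjusted p = 0.042) and the cytoskeletal gene ZNF185 (-1.15 ± 0.17, adjusted p = 0.017). At an unadjusted p under 0.05 the count was 1554, and DESeq2 called 42. The 7 calls were 0 without 0 h library 1, 2 or 4 and 1 without 72 h library 13, 17 without the 72 h libraries 15 and 27, and 265 without a filter on low counts. In MOLM13, edgeR called 0 genes at 72 h against 0 h, 1161 passed at an unadjusted p under 0.05, DESeq2 called 0, and 178 were called without a filter.

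Lists moved by small amounts at 72 h. In HL60, genes of late myeloid differentiation had a median of -0.19 (0 rose and 1 fell of 37, 0 and 4 adjusted over the list alone, camera adjusted p = 0.00031, and adjusted p = 0.62 with an estimated correlation), a call lost without 72 h library 14 (adjusted p = 0.0608). In MOLM13, stem cell genes had a median of -0.14 with 0 of 27 called (0 adjusted over the list alone), RUNX1 standing at -0.27 ± 0.10 and IKZF2 at -0.87 ± 0.34, both at an adjusted p = 0.55 (camera adjusted p = 0.0015, and adjusted p = 0.79 with an estimated correlation). G1/S and DNA replication genes there had a median of 0.14 with 0 of 31 called (0 adjusted over the list alone), CCNE1 at 0.32 ± 0.10 and UNG at 0.25 ± 0.09, both at an adjusted p = 0.55 (camera adjusted p = 0.0011, and adjusted p = 0.79 with an estimated correlation), a call lost without 0 h library 18 (0.130) or 72 h library 23 (0.0667). The test of the difference between the lines at 72 h called 0 genes in edgeR, with 648 at an unadjusted p under 0.05 and 1 in DESeq2. It called 27 without MOLM13 0 h library 19, 1 without HL60 72 h library 15 and 64 without a filter.

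From 12 to 72 h, several genes named for their change at 12 h moved the other way. Both comparisons use the same 12 h libraries, and these genes were chosen for large changes there. Part of the opposite move can therefore be built in. In HL60, ALDOC rose by 3.97 ± 0.36, FADS2 by 3.04 ± 0.24 and SPARC by 3.01 ± 0.15, and PLA2G7 (-3.20 ± 0.23), SEMA6B (-2.92 ± 0.26) and LGALS3 (-2.82 ± 0.20) fell, with adjusted p at most 3.8e-07 in edgeR. SREBP targets rose in 26 and fell in 0 of 31 cases (29 and 0 adjusted over the list alone, camera adjusted p = 4.1e-18, and adjusted p = 0.13 with an estimated correlation), hypoxia targets rose in 19 and fell in 1 of 33 (21 and 1, 8e-07 and 0.39 in the same order), and G1/S genes rose in 21 and fell in 0 of 31 (22 and 0, 3.2e-08 and 0.13). In MOLM13, AGXT rose by 5.39 ± 0.45, TBC1D30 by 4.203 ± 0.30, CHAC1 by 3.41 ± 0.64, TMEM45A by 3.33 ± 0.35 and ADM by 3.30 ± 0.30, and TNFSF14 (-1.13 ± 0.21), SLC22A4 (-1.08 ± 0.14) and PRICKLE1 (-0.97 ± 0.18) fell, with adjusted p at most 0.0026 in edgeR. CHAC1 ranged from 104 to 541 counts over the MOLM13 72 h libraries. Hypoxia targets rose in 20 and fell in 0 of 33 cases (20 and 0, 2.1e-09 and 0.18), SREBP targets in 18 and 0 of 31 (24 and 0, 2.5e-13 and 0.13) and integrated stress genes in 12 and 0 of 28 (23 and 0, 4.5e-08 and 0.46). G1/S genes fell in 18 and rose in 0 of 31 cases (21 and 1, 2.5e-13 and 0.081), and heat shock genes fell in 15 and rose in 2 of 25 (17 and 3, 3.7e-08 and 0.13).

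Of 14128 genes, 5154 were called in HL60 between 12 and 72 h, 2708 higher and 2446 lower, and 1602 in MOLM13, 885 higher and 717 lower. These became 7417 and 2896 without libraries 15 and 27, and the MOLM13 count ranged from 707 to 1094 when 1 library was left out, as 816, 738 and 707 without 12 h libraries 20, 21 and 22. It was 1094, 1001 and 876 without 72 h libraries 23, 25 and 27.

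Before vitamin C, the lines differed in myeloid genes. HL60 was higher in MPO (8.16 ± 0.18 log2), MS4A3, a gene of granulocyte precursors (5.96 ± 0.15), SESN3 (4.71 ± 0.26) and ANXA1 (4.42 ± 0.12), and MOLM13 was higher in ANXA4 (-5.54 ± 0.10), the receptor gene RET (-5.08 ± 0.14), SDC2 (-4.85 ± 0.12) and BMI1, a repressor that maintains stem cells (-4.46 ± 0.17), with adjusted p at most 5e-12 in edgeR (n = 3 per group). CLEC5A was at least 2565-fold and PITX1 at least 1608-fold higher in HL60, and CRISPLD1 at least 1196-fold and ATP10A at least 1040-fold lower, against a floor of 3 counts over the group with none. Late myeloid genes were higher in 26 and lower in 8 of 37 cases in HL60 (26 and 8 adjusted over the list alone, camera adjusted p = 5e-05, and adjusted p = 0.35 with an estimated correlation). Stem cell genes were higher in 4 and lower in 21 of 27 (4 and 21, 5e-05 and 0.22 in the same order), interferon genes in 2 and 31 of 40 (2 and 31, 5e-05 and 0.38) and MHC class II genes in 0 and 10 of 10 (0 and 10, 0.0028 and 0.30). In all, 9563 of 14128 genes differed, 4625 higher and 4938 lower in HL60.

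In the mouse cells, Tet2 itself was examined before any comparison, because the labels state that doxycycline turned its shRNA off. Tet2 averaged 28.5 ± 3.85 CPM in the libraries labelled minus and 41.0 ± 12.7 CPM in those labelled plus at day 3, 73.3 ± 13.4 and 76.5 ± 17.5 CPM at day 7, 52.4 ± 7.88 and 35.0 ± 0.26 CPM at day 10, and 56.6 ± 5.59 and 29.9 ± 7.59 CPM at day 14 (n = 2 per group). In single libraries it stood at 29.6 and 24.98 CPM of raw total in the minus and 49.8 and 31.01 CPM in the plus libraries 39 and 46 of day 3. The other pairs, in the same order, held 89.1 and 64.5 against 66.4 and 92.3 CPM at day 7, 48.2 and 62.9 against 35.6 and 34.9 CPM at day 10, and 60.2 and 51.6 against 22.7 and 33.1 CPM at day 14. Tet2 was thus lower in the libraries labelled plus at days 10 and 14, against the direction the label implies, and over the 4 days it was not called (-0.23 ± 0.13, adjusted p = 0.59, edgeR). At day 14 it was lower in the libraries labelled plus with the number 39 or 46 as a block (-0.92, adjusted p = 0.040) and not called without the block (adjusted p = 0.18). The libraries are therefore named by their labels throughout. Tet1 (0.00 ± 0.29), Tet3 (-0.04 ± 0.09) and Tdg (0.11 ± 0.13) were not called over the 4 days, with adjusted p of at least 0.82.

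Mki67, a marker of proliferation, averaged 487 CPM at day 3, 2.08 at day 7, 488 at day 10 and 42.4 at day 14 in the libraries labelled minus, and 461, 2.50, 520 and 139 CPM in those labelled plus (n = 2 per group). Day 10 library 46 labelled minus stood apart, with Malat1 at 2126 CPM against 563 CPM in library 39. In every fit without day 10 minus library 39, library 46 alone stood for its group. Counts from those fits, given below, rest on it and do not show that library 39 hid changes.

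**Figure D3:**
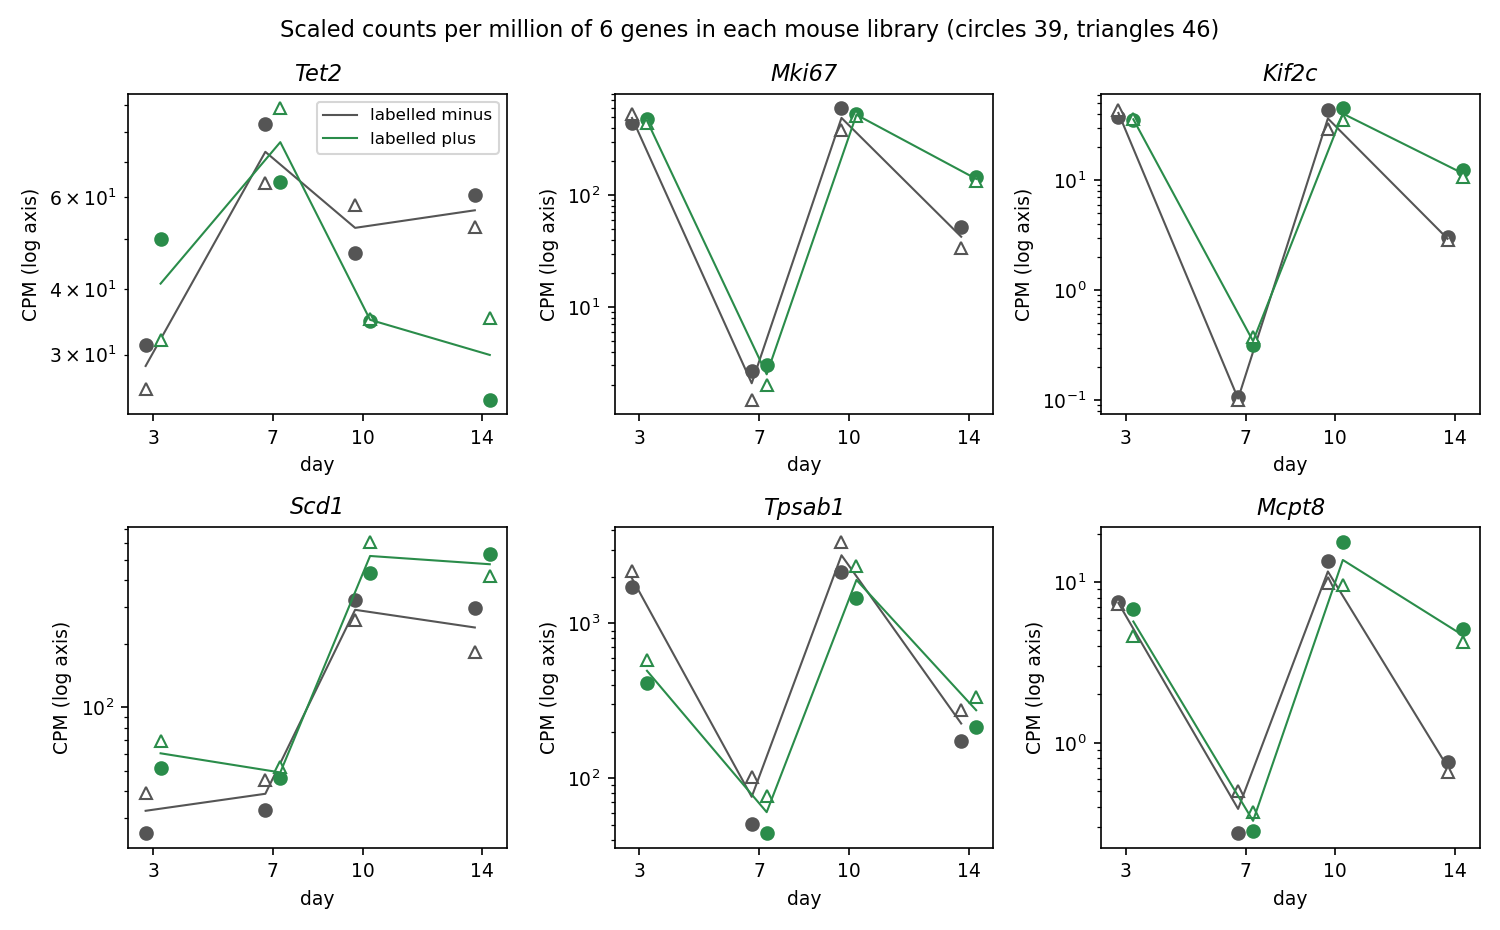
CPM after scaling (log axis) of 6 genes in each of 16 mouse libraries by day, with the libraries labelled minus in grey, those labelled plus in green, filled circles for number 39, open triangles for 46 and lines through the group means (n = 2). Kif2c averaged 2.93 CPM in the minus and 11.6 CPM in the plus libraries at day 14.

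Averaged over the 4 days and with the library number as a block, 12 of 33 SREBP targets and 7 of 31 G2/M genes were called higher in the libraries labelled plus, and 0 of either without the block. The mean does not describe every day. The mitotic gene Kif2c averaged 40.8 CPM in minus and 35.8 CPM in plus at day 3, and 36.4 and 40.3 CPM at day 10. At day 7 it held 4 and 5 counts in the minus libraries and 10 in each plus library. At day 14 it averaged 2.93 and 11.6 CPM. In the blocked test, the desaturase genes Scd1 (0.77 ± 0.13) and Scd2 (0.57 ± 0.09), the sterol synthesis genes Cyp51 (0.43 ± 0.06) and Acat2 (0.40 ± 0.06), Idh1 (0.43 ± 0.07), which supplies NADPH, and the mitotic spindle gene Tpx2 (0.58 ± 0.08) were higher, and the mast cell tryptase gene Tpsab1, which has a close paralog, was lower (-0.64 ± 0.07), with adjusted p at most 0.012. At day 14 alone Tpsab1 stood the other way, at 226 ± 73.3 CPM in the minus and 275 ± 84.4 CPM in the plus libraries (n = 2 per group), higher in plus in both numbers. The actin-binding gene Tpm4 (1.14 ± 0.16), Homer2 (1.08 ± 0.18), Serpina3f (0.99 ± 0.14), a member of a gene cluster with similar sequences, Slit2 (0.92 ± 0.15) and the integrin gene Itgb2 (0.57 ± 0.08) were also higher, and Dmwd (-0.75 ± 0.11), Rtn4r (-0.64 ± 0.09), Trim46 (-0.63 ± 0.09) and the lectin gene Clec10a (-0.59 ± 0.08) lower, again at adjusted p of at most 0.012. The kinesin gene Kif2c (0.91 ± 0.15, adjusted p = 0.012) lost its call without day 7 plus library 46 (adjusted p = 0.0521), and Ccnb1 (0.61 ± 0.12, adjusted p = 0.023) kept its call in 8 of 18 alternatives.

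With the block, 243 of 13766 genes passed, 150 higher and 93 lower. Without it, edgeR called 0, with 1363 at an unadjusted p under 0.05, 179 in DESeq2, 148 without a filter on low counts and 369 without day 10 minus library 39. The blocked count was 2434 without that library, and 40 at its lowest, without day 14 minus library 46. Of 33 SREBP targets, 12 were higher and 0 lower with the block (22 and 0 adjusted over the list alone), and 0 were called without it (21 and 0 adjusted over the list alone, camera adjusted p = 3.3e-21, and adjusted p = 0.12 with an estimated correlation). Of 31 G2/M genes, which include Top2a (0.48 ± 0.08 with the block), 7 were higher and 0 lower with the block (27 and 0 adjusted over the list alone), and 0 were called without it (25 and 0 adjusted over the list alone, camera adjusted p = 2.9e-16, and adjusted p = 0.33 with an estimated correlation). Heat shock genes were called higher as a list (camera adjusted p = 1.4e-05, and adjusted p = 0.33 with an estimated correlation) and replication-dependent histone genes lower (camera adjusted p = 0.0035, and adjusted p = 0.33 with an estimated correlation), with 0 members of either called (2 higher and 1 lower adjusted over the lists alone).

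At day 14, mitotic genes were higher in the libraries labelled plus. Kif2c averaged 2.93 ± 0.137 CPM in the minus and 11.6 ± 1.25 CPM in the plus libraries (1.98 ± 0.20, adjusted p = 0.0026, n = 2 per group), and the mitotic kinase gene Plk1 was higher by 1.96 ± 0.38 (adjusted p = 0.042). All of the 31 measured G2/M genes were called higher with the block and 27 without it (31 and 0 adjusted over the list alone in each), with a median of 1.58 log2 without the block (camera adjusted p = 6.1e-57, and adjusted p = 0.053 with an estimated correlation). The basophil protease gene Mcpt8 (2.72 ± 0.38, adjusted p = 0.0086) and Tcrg-C1, of the T cell receptor gamma locus, whose constant genes are alike (2.27 ± 0.44, adjusted p = 0.040), were higher, and the transcription factor gene Sox12 was lower (-1.34 ± 0.27, adjusted p = 0.044). With the block, Tpm4 (3.07 ± 0.27) and the collagen gene Col18a1 (2.09 ± 0.30) were higher at adjusted p of 5.6e-05 and 0.0011. SREBP targets were higher in 4 and lower in 0 of 33 cases (19 and 0 adjusted over the list alone, camera adjusted p = 9.2e-22, and adjusted p = 0.053 with an estimated correlation), and in 15 and 0 with the block. G1/S genes were higher in 7 and lower in 0 of 31 (15 and 1 adjusted over the list alone, camera adjusted p = 1.9e-14, and adjusted p = 0.24 with an estimated correlation), and in 12 and 0 with the block.

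In all, 124 of 13766 genes were called at day 14 without the block, 117 higher and 7 lower, and 517 with it, 425 higher and 92 lower. Leaving out 1 day 14 library gave 38 (minus 39), 0 (minus 46), 7 (plus 39) or 11 (plus 46) calls without the block and 153 to 192 with it, and 961 with the block and without day 10 minus library 46. A fit to the day 14 libraries alone called 0, DESeq2 called 343, and 63 genes passed at a fold change above 1.2. The plus libraries of this day held 75366205 and 53835698 counts and the minus libraries 29229858 and 37116864.

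At day 3, the tryptase gene Tpsab1 averaged 1954 ± 320.3 CPM in the minus and 495 ± 119 CPM in the plus libraries (-1.999 ± 0.14, adjusted p = 1.2e-05 with the block, n = 2 per group), and the transglutaminase gene Tgm2 was higher in the plus libraries (2.04 ± 0.19, adjusted p = 0.00025 with the block). With the block, 132 of 13766 genes passed, 75 higher and 57 lower, but only 2 to 4 when 1 day 3 library was left out, and 1000 without day 10 minus library 46. Without the block, edgeR called 0 genes at day 3 (1517 at an unadjusted p under 0.05, 241 in DESeq2, 42 without a filter), 0 at day 7 (60, and 0 in DESeq2) and 0 at day 10 (1190, and 2 in DESeq2). The block gave 0 at days 7 and 10, and the unblocked day 10 count was 2222 without minus library 39. The cholesterol biosynthesis and SREBP targets were called higher as a list at day 7 (median 0.10, camera adjusted p = 9.6e-08, and adjusted p = 0.47 with an estimated correlation), except without minus library 39 (adjusted p = 0.149), and at day 10 (median 0.31, camera adjusted p = 1.2e-07, and adjusted p = 0.69 with an estimated correlation), with 0 members called at either day. The difference between the labels was tested for change with day: 11 of 13766 genes passed, 162 with the block, including Kif2c, the kinase genes Aurkb and Cdk1 and the cytokinesis gene Cit, whose differences at day 14 exceeded those at day 3 by 2.17, 1.93, 1.66 and 1.72 log2 (adjusted p = 0.045 for each). The 11 calls were 0 with RLE size factors and ranged from 0 to 58 when 1 of the 16 libraries was left out (58 without day 10 minus library 39, 1 without day 10 minus library 46 and 0 without any other). The 162 blocked calls became 3126 without day 10 minus library 39, 442 without day 10 minus library 46 and 263 without day 10 plus library 39. They fell to 52 and 36 without day 14 minus library 39 or 46, to 50 and 39 without day 14 plus library 39 or 46, to 107 without day 3 minus library 46, and to 102 and 95 without day 3 plus library 39 or 46.

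From day 3 to day 14, mitotic and ribosome biogenesis genes fell in both labels. In the libraries labelled minus, the ribonucleotide reductase gene Rrm2 (-4.79 ± 0.33) and the immediate-early genes Egr4 (-6.45 ± 0.46) and Fosb (-5.27 ± 0.46) fell and the transketolase-like gene Tktl1 rose (4.27 ± 0.61), with adjusted p at most 0.00036 in edgeR (n = 2 per group). In those labelled plus, Egr4 (-4.93 ± 0.41), Fosb (-5.14 ± 0.45) and the antiproliferative gene Btg2 (-4.09 ± 0.45) fell, and Scd1 (2.98 ± 0.31), Aldoc (2.89 ± 0.28) and Card6 (3.08 ± 0.18) rose, with adjusted p at most 0.00019. G2/M genes fell in 31 of 31 cases in the minus libraries (31 adjusted over the list alone, camera adjusted p = 2.1e-29, and adjusted p = 0.14 with an estimated correlation) and in 30 of 31 in the plus libraries (30, 3e-29 and 0.11 in the same order). MYC targets fell in 30 of 31 (30, 5.5e-18 and 0.14) and 26 of 31 (27, 2.4e-21 and 0.11), and immediate-early genes in 18 of 24, with 1 higher (18 and 1, 9.8e-10 and 0.14), and 17 of 24 (18, 2.5e-11 and 0.11). SREBP targets rose in 18 and fell in 0 of 33 cases in the plus libraries (21 and 0, 1.5e-10 and 0.11) and rose in 11 and fell in 2 in the minus libraries (11 and 3, 0.030 and 0.54), where the list call was lost without day 14 library 39 (adjusted p = 0.224). Scd1 went from 60.6 ± 12.6 to 477 ± 83.2 CPM in the plus and from 32.3 ± 9.94 to 239 ± 78.95 CPM in the minus libraries.

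Of 13766 genes, 4639 were called between these days in the minus libraries (2226 higher, 2413 lower) and 2474 in the plus libraries (1063 higher, 1411 lower), or 6537 and 4391 with the block. Leaving out 1 library gave 2956 (day 3 library 39), 2889 (day 3 library 46), 2750 (day 14 library 39) or 3509 (day 14 library 46) calls in the minus and 1106, 1612, 937 or 1239, in the same order, in the plus libraries. Mki67 was itself lower at day 14 than at day 3 and did not fall steadily, as given above, so these values hold for this pair of days.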

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

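Of the tests in this part, the thinning was chosen only after the result was seen. The values below differed between lines or days by a test of the difference itself, and groups of 2 or 3 libraries were too small for a test of single libraries.

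The response at 12 h differed between HL60 and MOLM13 for 2628 genes in edgeR. Single genes with large differences, HL60 minus MOLM13 in log2, were LGALS3 (3.07), FGL2 (2.41), MT1X (2.29), MT2A (2.19), ALDOC (-2.69), TFRC (-2.31) and HSPG2 (-2.26). Lists with a lower response in HL60 were G1/S and replication (median -0.95), early granule genes (-0.85), DNA damage (-0.71), SREBP targets (-0.60), glycolysis (-0.44), p53 targets (-0.32) and base excision repair (-0.21). Of these, G1/S held with an estimated correlation (adjusted p = 0.0075), and the others did not, at adjusted p = 0.52, 0.15, 0.51, 0.52, 0.13 and 0.70 with an estimated correlation, in the order given. Lists with a higher response were the integrated stress response (0.73), NF-kB targets (0.64), late myeloid genes (0.61) and immediate-early genes (0.18), and none of these 4 held, at adjusted p = 0.78, 0.52, 0.70 and 0.78 with an estimated correlation. Of 50 splits drawn from 200 possible ones, 4, the real one included, gave as many genes, and the highest other gave 3913. The 3 others kept the times of at least 1 line whole, so they hold that line's own response. They do not measure chance for a difference. The 38 that mixed the times of both lines gave 0 at most. Mixing adds each line's change with time to the spread and so lowers the count, and these do not measure chance either. At 72 h the G1/S median differed by -0.16 (camera adjusted p = 0.0031) and the glycolysis median by -0.16 (camera adjusted p = 0.036), neither of which held (adjusted p = 0.90 with an estimated correlation for each), with 0 genes called in edgeR (648 at an unadjusted p under 0.05, 1 in DESeq2). A count of 0 is reached by all 50 splits drawn, so they say nothing on chance, and the highest, 2186, came from a split that kept the times of at least 1 line whole, against 59 at most where both were mixed.

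The difference between the mouse labels changed with day for 11 genes in edgeR, among them Kif2c (2.17), Aurkb (1.93), Cdk1 (1.66) and Cit (1.72), given as day 14 minus day 3 in log2. The mitotic genes behind this were higher at day 14 in the libraries labelled plus. Thinning every library to the smallest total kept 85.2% of the calls of mitotic genes at day 14 (23 of 27). This argues against library size as the whole cause of the day 14 difference. The test of change with day itself had 0 calls after thinning, so library size was not set aside for it. What stays open is a difference in growth of the kind seen between days: the day 14 difference correlated across 13766 genes, which are not independent replicates, with the change from day 7 to day 10 in the minus libraries at r = 0.488, between the bounds of 0.2 and 0.5 set for it. Doxycycline or the shRNA may also be behind it, which was not tested apart from growth, and Tet2 at day 14 went against the label.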

How the results depend on the processing

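Removal of the length trend, omission of the 72 h libraries 15 and 27 or of day 10 minus library 46, and thinning were chosen only after the results were seen. Of the counts under the alternatives, 228 lay within 1.5 times of the 22 reported and 121 did not. Of the named genes' values under the alternatives, 3360 kept direction and side of the threshold, 142 lost and 82 gained a call, and 2 reversed, both TET3 in HL60 at 12 h, from -0.33 to 0.24 with the length trend removed and to 0.24 with libraries 15 and 27 left out as well. Fits that leave out a library use the spread of the others, and a lone library is assumed to vary like the other groups. The highest such counts for the mouse mean, day 10 and the change with day came without day 10 minus library 39. That group was then left with library 46, which stood apart. Fewer libraries, fewer genes or a stricter test account for lower counts by construction. The 72 h libraries 15 and 27 are in no group of the 12 h comparisons with 0 h. Leaving them out thus moved those counts only through what the fit shares over libraries, its spread, scaling and filter. The cause was not tested elsewhere. In the self-test of the HL60 72 h comparison 43.3% of 1.5-fold changes were recovered, so small changes were often not recovered. With every library thinned, 1512 genes lay there at an unadjusted p under 0.05, against 1554, so depth within this range was not shown to set that limit. No paired analysis was possible because no human replicate number was shared between groups.

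With an estimated correlation, the 160 list calls became 1. HL60 at 72 h against 0 h went from 7 to 17 without libraries 15 and 27, 19 with the length trend removed as well, 12 with the trend removed alone, 42 in DESeq2, 4 thinned, 4 in the line alone, 1 above 1.2-fold, 265 without a filter and 0 to 10 with 1 library left out. HL60 at 72 h against 12 h went from 5154 to 3044 above 1.2-fold. MOLM13 at 12 h went from 3784 to 6004 without libraries 15 and 27, 1473 above 1.2-fold and 2263 to 3347 with 1 library left out. MOLM13 at 72 h went from 0 to 178 without a filter, and 72 h against 12 h from 1602 to 2896 without libraries 15 and 27, 2588 with the trend removed as well, 2509 in the line alone, 408 above 1.2-fold and 707 to 1094 with 1 library left out. The line difference at 12 h went from 2628 to 4649 and 4430 in the same order and 1534 above 1.2-fold, and at 72 h from 0 to 1 and 4, 1 in DESeq2, 64 without a filter and 0 to 27 with 1 library left out.

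In the mouse, the number as a block moved the mean over days from 0 to 243, day 3 from 0 to 132, day 14 from 124 to 517, the change with day from 11 to 162 and day 14 against day 3 in plus from 2474 to 4391. Days 7 and 10 stayed at 0 in edgeR, with 101 and 2532 genes at an unadjusted p under 0.05 with the block. Without it these were 60 and 1190, and DESeq2 called 0 and 2. Without the block, DESeq2 gave 179, 241, 343 and 242 for the mean, day 3, day 14 and the change with day, and no filter gave 148, 42, 339, 263 and, at day 10, 34. Thinning gave 1 at day 3 and 0 for the change with day, RLE size factors 0 for the latter, the day 14 libraries alone 0, and the test above 1.2-fold 63 at day 14 and 1464 for day 14 against day 3 in plus. With 1 library left out, the ranges were 0 to 369 (mean), 0 to 2222 (day 10), 0 to 38 (day 14), 0 to 58 (change with day), 937 to 1612 (day 14 against day 3 in plus) and 2750 to 3509 (in minus). In the blocked fits they were 40 to 2434 (mean), 2 to 4 (day 3), 153 to 192 (day 14) and 36 to 3126 (change with day), and without day 10 minus library 46 the block gave 1000 at day 3, 961 at day 14 and 442 for the change with day.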

Other observations

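Of the tests in this part, the removal of the length trend, the omission of libraries 15 and 27 and the thinning were chosen only after the result was seen.

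Other gene lists held called members at 12 h without a call of the list. In HL60 at 12 h, genes of vitamin C uptake and iron handling fell in 9 and rose in 6 of 17 cases (10 and 6 adjusted over the list alone, camera adjusted p = 0.52), with FTH1 rising by 1.45 ± 0.19. Interferon genes there fell in 10 and rose in 3 of 40 cases (camera adjusted p = 0.41), and p53 targets fell in 9 and rose in 3 of 22 (camera adjusted p = 0.27). In MOLM13 at 12 h, p53 targets rose in 7 and fell in 2 of 22 cases (camera adjusted p = 0.052) and NF-kB targets fell in 10 and rose in 3 of 26 (camera adjusted p = 0.065). At 0 h, mast cell and basophil genes were higher in HL60 than in MOLM13 in 6 and lower in 2 of 8 cases, with a median of 4.85 log2 (camera adjusted p = 0.014, and adjusted p = 0.22 with an estimated correlation).

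Many genes changed at 12 h in both lines. With the length trend removed, 76.7% of the calls in HL60 and 86.3% in MOLM13 kept call and sign, and with every library thinned to the smallest total 94.1% and 90.3% did, so neither the trend nor library size accounts for the whole. Time in culture or handling could account for any part of it and cannot be told apart from vitamin C, since 0 libraries of HL60 and 0 of MOLM13 were sampled at 12 h without it. The real groups gave 6688 calls in HL60 and 3784 in MOLM13, and of the 10 splits of each 6 libraries 1, the real one, gave as many, with 0 as the highest of the others. These splits are too few for a share under 0.05.

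Few genes were called at 72 h against 0 h, which does not show that few differed. Library 15 of HL60 and library 27 of MOLM13 could have hidden changes by adding spread. Without both and with the length trend removed, the calls at 72 h were 0.263% (19) of the 7211 at 12 h in HL60 and 0% (0) of the 5406 in MOLM13 in edgeR, which argues against them as the whole cause. The change at 12 h nevertheless correlated, across genes that are not independent replicates, with the difference of library 15 from the other 72 h libraries at r = 0.50 (0.39 with the length trend removed) and with that of library 27 at r = 0.084 (0.0072 with it removed). With both libraries out and the trend removed, 1995 genes in HL60 and 1668 in MOLM13 lay at an unadjusted p under 0.05 in edgeR. The self-test recovered 43.3% of 1.5-fold changes at 72 h in HL60 and 40.3% in MOLM13. Whether the response ended by 72 h or the vitamin C was used up was not tested.

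Other splits into 3 and 3, too few for a share under 0.05 with 10 each, gave the following. HL60 at 72 h against 0 h had 7 calls and a highest other of 0 (1 split as large), HL60 at 72 h against 12 h 5154 and 1200 (1), MOLM13 at 72 h against 12 h 1602 and 0 (1), and the lines at 0 h 9563 and 0 (1). MOLM13 at 72 h against 0 h had 0 and 122, and over the mouse days without the block the real count was 0 and the highest of 100 splits drawn from 648, which did not keep the pairs of numbers, was 1418. A count of 0 is reached by every split (10 and 100), so these say nothing on chance, and why other splits gave high counts was not tested. With the number as a block, minus and plus were exchanged within pairs of the same day and number. Of 100 exchanges drawn from 128, 1, the real one, gave as many as the real 243, and the highest other gave 176. Exchanging 1 number of a day alone adds that day's difference to the spread and so lowers the count. The rank therefore bears on the absence of any difference between the labels, not on the mean over days. For any such difference, chance is unlikely if the pairs of different days are independent. The labels do not state this, and chance was not excluded.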
